A study of Brassica napus with 12 samples.

How the data were processed

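The series asked how bacterial ACC deaminase alters plant gene expression, per the labels. Seeds of Brassica napus were soaked for 1 h in bacteria at an OD600 of 0.5 or in a control solution. The bacterial genotype was ACD+ or ACD-; by the series title the letters refer to ACC deaminase, and what the ACD- genotype lacks is not described further. Seedlings grew in vermiculite with nutrient solution under 12 h of light at 20 °C, and shoots and roots were dissected on day 6. The bacterial strain is not given in the sources used here. The labels do not state whether the 3 replicates came from separate plantings, nor whether the untreated RNA was shared between the ACD+ and ACD- arrays of a tissue. All p-values therefore measure the spread between these samples.

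Each of 12 slides of an Agilent Arabidopsis long-oligonucleotide array carried 1 hybridisation of treated against untreated RNA of the same tissue, with 10 µg of total RNA labelled directly. There were 3 arrays in each of 4 groups (shoot or root, ACD+ or ACD-). Replicates 1 and 2 carried the treated RNA in Cy5, and replicate 3 carried it in Cy3. The probes were designed for Arabidopsis, so several related Brassica genes can share a probe. Gene identities below are the Arabidopsis loci and product names given in the array files; 8884 probes had no product name. A slide had 22575 spots: 21500 gene probes with 1 probe per locus, 913 positive and 162 negative control spots.

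The deposited scanner files hold spot and background intensity in both channels and the percent of saturated pixels, per the file headers (GenePix Pro 6.0.1.27). Of 17 files 16 were used; 5 samples had 2 files. The file left out belonged by its name to replicate 3 of the ACD+ shoots. Its header named the image of replicate 3 of the ACD- shoots, and its log ratios correlated at r = 0.992 with the other file read from that image but at r = 0.558 with the other file of its own sample. The deposited matrix holds log2 ratios, which the authors normalised with limma, per the submitters' processing notes (version not given). Its values for that sample correlated at r = 0.946 with the ratio computed with the misplaced file and at r = 0.797 without it. In the deposited matrix the ACD+ and ACD- shoots of replicate 3 correlated at r = 0.865; without that file and without background correction the correlation was r = 0.524. The fit therefore started from the scanner files, and the matrix served as an alternative.

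The matrix had 11 filled columns, while the column of replicate 2 of the ACD- roots was empty. Column medians were 0.0382, 0.0447 and -0.0338 in ACD+ shoots, 0.0366, 0.0377 and -0.0406 in ACD- shoots, 0.0244, 0.0161 and 0.00424 in ACD+ roots, and 0.0183 and 0.00803 in ACD- roots (replicates 1 and 3). The columns correlated with the ratios computed here at r = 0.797 to 0.964 with slopes of 0.833 to 1.14, which fixes their direction as treated over untreated and their log base as 2. The authors' background and centring settings stay unknown.

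Intensities were corrected for background with normexp (offset 50), and log2 ratios were normalised within each array by loess (span 0.3, controls given no weight, spots marked bad by the scanner left out) in limma 3.58.1 under R 4.3.3 with statmod 1.5.0. Repeat scans of the same sample were averaged. A probe was kept if it exceeded the background by 2 SD in at least 1 channel on 4 of the 6 arrays of either tissue. This filter removed none of the 21500 probes, which does not show that all exceeded the background in shoots (96.2% to 99.1% per shoot array). A missing value on any array was left as missing, which affected 555 probes. Shoot comparisons and the comparisons of shoot with root responses tested 21244 probes, and the others 21500.

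Ratios of all 12 arrays were fitted together, with 1 mean per group and a probe-specific dye term per tissue (6 coefficients, 6 residual degrees of freedom, 2.84 prior degrees of freedom). Each response was tested against 0, the ACD+ response against the ACD- response within each tissue, the root response against the shoot response within each genotype, and the genotype difference in roots against that in shoots. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are said to have risen, fallen or differed. Values are log2 ratios with standard errors of the fit, n = 3 arrays per group.

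The 19 gene lists held 410 genes, of which 402 had a probe: ethylene biosynthesis, ethylene signalling, ethylene responsive, auxin, jasmonate, salicylate and immunity, abscisate with drought and cold, gibberellin, cytokinin, photosynthesis, root markers, cell cycle, cell wall growth, phenylpropanoid and flavonoid, glucosinolate, nitrogen assimilation, oxidative stress, heat shock, and reference genes. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were also tested with the adjustment over the list alone. The groups, tests, lists, alternatives and naming rule were fixed before the data were examined; 4 alternatives were added later: the misplaced file averaged in, both dye-swapped shoot arrays left out, a filter at the 95th percentile of the negative controls, and the fixed replicate block with both tissues fitted together.

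Genes were named by rule. Each response and genotype difference gave 6 of its largest changes per direction, with adjusted p under 0.05 and 1 sign on every array. LUX (log2 1.83 in ACD- shoots, above AOS) was left out. Added were the 14 listed genes of smallest adjusted p and the highest and lowest ethylene biosynthesis gene. Where fewer than 6 genes passed in a direction, those with the smallest p filled up to 5, as values only. Members of the fixed lists are named as examples, chosen after their values were seen. The result of 1 list member is not reported here.

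Same-numbered ACD+ and ACD- arrays deviated together, but they share a dye orientation, and these deviations contain the dye effect. The correlations of their deviations from the group means were 0.394, 0.296 and 0.601 in shoots and 0.297, 0.183 and 0.798 in roots for replicates 1, 2 and 3, and were highest in the dye-swapped replicate. For the dye-free difference of replicates 1 and 2 the correlation was 0.0922 in shoots and -0.204 in roots. Between these replicates the pairing was thus weak or absent once the dye was removed. The labels do not say what the numbers share, and the dye term cannot be told apart from anything else particular to replicate 3. With the number as a fixed replicate block and both tissues fitted together, 1018 probes differed between ACD+ and ACD- shoots in place of 1506. With the block and shoots fitted alone 2 differed, and the small count of shoots fitted alone without the block is given in the results. Blocked values stand beside the results they change.

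Alternatives covered the dye term, background, normalisation, filters, averaging of scans, array weights, the authors' values, spread estimates, replicate block, thresholds, and leaving out each array in turn. Print-tip normalisation was not possible with 1 print block. A block by slide or scan day was not possible either, because each slide held 1 array and had its own day. Shoots were scanned in an earlier period than roots, so tissue and scan period cannot be told apart.

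The pipeline was tested on simulated data of 21500 genes with 200 changed probes. In the ACD+ shoot comparison it recovered 44.8% of changes of log2 0.5, 89.3% of changes of 1 and 97% of changes of 2, with 6 false among 164 calls; in the ACD- shoot comparison the shares were 53.4%, 89.3% and 98.5%, with 10 false among 174. The ACD+ root comparison gave 56.9%, 92% and 100% with 6 false among 175 calls, and the ACD- root comparison 48.3%, 88% and 98.5% with 10 false among 170. No probe was called in any comparison without a simulated effect and with equal spread in shoots and roots. A jasmonate list shifted by 0.5 in the simulated ACD+ shoot comparison had an adjusted p of 1.39e-50, and no other list passed.

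The measured spread was not equal. The median residual SD was 0.181 in shoots and 0.0601 in roots when each tissue was fitted alone, and 0.148 in the joint fit. In 20 simulations with these unequal spreads and no effect, the joint fit called on average 155.7 probes in ACD+ shoots, 137.7 in ACD- shoots and 157.85 in the difference between them. It called 0.1 in the ACD+ root comparison, 0.1 in the ACD- root comparison and 0.05 in their difference, and 3.25, 2.55 and 3.6 in the comparisons across tissues. The joint fit thus called too many probes in shoots and too few in roots, and total counts of each tissue fitted alone stand beside those of the joint fit. Counts of list members are from the joint fit only, so they carry the same excess in shoots and the same shortage in roots.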

Results

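The data comprised 12 two-colour arrays of treated against untreated seedlings, 3 per group. ACC deaminase cleaves ACC, the precursor of the plant hormone ethylene. Shoot arrays were dimmer than root arrays: median intensities were 2313 to 4411.5 in Cy5 and 2743.5 to 6454 in Cy3 in shoots, against 9495 to 17425 and 8856.5 to 17058.5 in roots. The median probe lay 2.02 to 6.13 times above the negative controls in shoots and 7.16 to 13.9 times in roots. Between 74.6% and 92.6% of probes exceeded the negative controls on shoot arrays, and 99.8% to 100% on root arrays. Log ratios spread more widely in shoots (SD 0.339 to 0.502) than in roots (SD 0.138 to 0.26). Photosynthesis probes were dimmer in roots than in shoots by a median log2 of -4.42, and root marker probes were brighter by 0.44. Replicates 1 and 2 of a group correlated at r = 0.531 in ACD+ shoots, 0.672 in ACD- shoots, 0.851 in ACD+ roots and 0.641 in ACD- roots. The dye-swapped replicate 3 correlated with them at 0.221 and 0.102, -0.16 and -0.259, 0.364 and 0.336, and 0.249 and 0.416 in the same order of groups.

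The response of shoots to ACD+ bacteria compares treated with untreated shoots. Over clock genes not seen beforehand, evening genes exceeded morning genes by a median log2 of at least 1.08 on every shoot array. Collection of treated and untreated shoots at different times of day therefore stays open as a source of shoot changes. The largest increases were in a CONSTANS-like B-box zinc finger gene (AT3G07650), by 4.94-fold (log2 2.3 ± 0.08, n = 3), and the pseudo-response regulator TOC1 (AT5G61380), a clock component, by 4.19-fold (2.07 ± 0.14). A glutamate decarboxylase (AT1G65960, 4.07-fold), which makes GABA, a nodulin-like gene (AT4G08300, 3.43-fold), a phosphofructokinase-like enzyme of sugar metabolism (AT5G47810, 3.39-fold) and a cold- and salt-responsive gene (AT4G30650, 3.05-fold) also rose. The largest decreases were in a cellulose synthase-like gene (AT4G16590, by 9.27-fold, log2 -3.21 ± 0.17), a phosphoethanolamine N-methyltransferase of phospholipid synthesis (AT1G73600, by 7.88-fold) and chalcone synthase (CHS), the entry enzyme of flavonoid synthesis (by 7.07-fold, log2 -2.82 ± 0.12). A myo-inositol-1-phosphate synthase (AT4G39800, by 6.23-fold), the morning clock gene CCA1 (by 6.15-fold), the salt tolerance-like gene AT2G31380 (by 5.51-fold) and the salicylate marker PR1 (by 5.3-fold) fell as well. In all, 2601 genes rose and 2471 fell among 21244 tested. When shoots were fitted alone 652 rose and 712 fell. The total of 5072 became 2904 without replicate 3 of this group. AT4G08300 did not pass without a dye term (adjusted p = 0.0836, 1.13e-05 to 0.0836 over the alternatives).

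Auxin genes rose as a group in ACD+ shoots (mean log2 0.294, adjusted p = 2.08e-05; adjusted p = 0.0992 with an estimated correlation). Of 38 measured, 19 rose and 1 fell over all genes, and 21 rose and 2 fell when adjusted over the list alone. The auxin-inducible repressors IAA19 (2.27-fold, log2 1.18 ± 0.06), IAA1 (0.78), IAA5 (0.74 ± 0.08) and IAA2 (0.70 ± 0.06), the growth-related SAUR19 (0.75) and the auxin influx carrier AUX1 (0.72 ± 0.08) rose, whereas IAA7 fell (-0.38). Heat shock genes fell (mean log2 -0.698, adjusted p = 2.91e-06; adjusted p = 0.0903 with an estimated correlation): 6 of 10 fell and 1 rose over all genes, and 8 fell and 1 rose when adjusted over the list alone. The chaperones HSP17.4 (-2.22 ± 0.19), HSP101 (-1.3 ± 0.07), HSP17.6A (-1.09 ± 0.08) and HSP17.6II (-1.01 ± 0.10) were among those that fell, and the chloroplast protein HSP21 rose (1.45 ± 0.17). The fall of HSP17.6A did not pass with the authors' values (-0.099) or with the misplaced file averaged in (-0.347).

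Phenylpropanoid and flavonoid genes formed the largest group decrease in ACD+ shoots (mean log2 -0.799, adjusted p = 6.76e-09; adjusted p = 0.0903 with an estimated correlation). Of 22 measured, 16 fell and 0 rose over all genes (limma; 17 fell and 2 rose when adjusted over the list alone), including CHS, the lignin methyltransferase COMT1 (-2.15), flavonol synthase FLS1 (-1.51), the anthocyanin enzyme LDOX (-1.94 ± 0.39) and the phenylalanine ammonia-lyases PAL1 (-1.11) and PAL2 (-1.19). Oxidative stress genes fell (mean log2 -0.504, adjusted p = 0.00036; adjusted p = 0.202 with an estimated correlation), with 8 of 14 lower and 0 higher in limma by either adjustment, over all genes or adjusted over the list alone. Among these were the glutathione transferases GSTF7 (-1.75) and GSTF2 (-1.20), catalase CAT2 (-1.52 ± 0.22) and the superoxide dismutase CSD1 (-0.76). Glucosinolate genes fell (mean log2 -0.28, adjusted p = 0.000319; adjusted p = 0.0832 with an estimated correlation), with 10 of 26 lower and 1 higher both over all genes and when adjusted over the list alone. COMT1 and GSTF2 had saturated pixels on 4 arrays each. The nitrilase NIT4 (-1.11) and the glucosinolate P450 enzymes CYP83A1 (-0.95) and CYP83B1 (-0.85) fell, and the epithiospecifier ESP rose (0.82).

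Ethylene lists did not pass as groups in ACD+ shoots, although single members moved. Of 17 ethylene biosynthesis genes 4 rose and 2 fell over all genes, and 5 rose and 2 fell when adjusted over the list alone (mean log2 0.215, median 0.02, adjusted p = 0.352). The ACC oxidases ACO4 (2.92-fold, log2 1.54 ± 0.10) and ACO5 (1.14 ± 0.14) and the ACC synthases ACS8 (0.85 ± 0.09) and ACS5 (0.64 ± 0.05) rose, while ACO3 (-0.43 ± 0.13) and ACS11 (-0.21) fell. ACO4 was missing on 1 of the 3 arrays, so its value rests on 2. The fall of ACO3 was -0.034 without replicate 3 of this group, and 15 of 32 alternatives ended its call (adjusted p 0.000312 to 0.87). Of 11 ethylene signalling genes 3 rose and 1 fell by both adjustments, over all genes and adjusted over the list alone (mean log2 0.126, adjusted p = 0.136). The transcription factors EIL1 (0.62 ± 0.06) and EIN3 (0.45 ± 0.05) and the kinase CTR1 (0.43 ± 0.09) rose, and the receptor ETR2 fell (-0.33 ± 0.09). Of 16 ethylene responsive genes 3 fell, also when adjusted over the list alone (mean log2 -0.126, adjusted p = 0.128): RAV1 (-0.44), ERF1 (-0.27 ± 0.07) and TEM1 (-0.23).

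Among the remaining lists in ACD+ shoots, 3 jasmonate genes rose and 5 of 24 fell, also when adjusted over the list alone (mean log2 -0.155, adjusted p = 0.128), with LOX2 (-0.89) and THI2.1 (-0.86) lower and allene oxide synthase AOS higher (0.31). Of 26 salicylate and immunity genes 5 fell by either adjustment, including adjusted over the list alone (mean log2 -0.203, adjusted p = 0.0627), among them PR1 (-2.41), PR2 (-0.67) and PAD4 (-0.60). Cytokinin genes split into 3 higher and 6 lower of 15 (3 and 8 adjusted over the list alone; adjusted p = 0.0935), with ARR16 higher (0.82) and CRF2 lower (-0.55). Nitrogen assimilation genes split into 3 higher and 5 lower of 12, also adjusted over the list alone (adjusted p = 0.149), with glutamine synthetase GLN1;1 (-1.50 ± 0.15) and nitrate reductase NIA1 (-0.74) lower. Cell wall growth genes split into 5 higher and 7 lower of 27 (6 and 8 adjusted over the list alone; mean -0.071, median 0.079, adjusted p = 0.897), with the xyloglucan enzymes TCH4 (-1.92) and XTH20 (-1.08) lower and XTH18 higher (0.88). Abscisate, drought and cold genes split into 3 and 4 of 27 (3 and 5 adjusted over the list alone; adjusted p = 0.751), with COR413PM1 higher (0.82) and RD26 lower (-0.91). Gibberellin genes split into 3 and 3 of 14 (3 and 5 adjusted over the list alone; adjusted p = 0.751; mean 0.004, with median and test pointing down). Photosynthesis (1 higher and 1 lower of 56; 0 and 1 adjusted over the list alone; adjusted p = 0.611), cell cycle (1 and 1 of 17; 0 and 1 adjusted over the list alone; adjusted p = 0.844), and root marker genes (0 and 3 of 17; 0 and 1 adjusted over the list alone; adjusted p = 0.379) did not pass as groups, nor did reference genes (2 and 0 of 9, also adjusted over the list alone; mean 0.174, adjusted p = 0.0627). The photosynthesis enzyme PRK fell (-0.72), and the reference gene UBC9 rose (0.46).

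For the response of shoots to ACD- bacteria a difference in collection time stays open too. The strongest increases were in 2 small heat shock proteins, HSP17.6II (4.95-fold, log2 2.31 ± 0.10, n = 3) and HSP17.6A (4.71-fold, 2.24 ± 0.08). A dioxygenase-family gene (AT3G11180, 4.17-fold), TOC1 (3.76-fold), AT3G07650 (3.64-fold) and AOS, an enzyme of jasmonate synthesis (3.46-fold, 1.79 ± 0.06), also rose. A PR1-like gene (AT2G14580) fell by 14-fold (log2 -3.81) and PR1 by 11.9-fold (-3.58 ± 0.06), followed by the xyloglucan enzyme AT4G25820 (by 5.64-fold), the AP2-domain gene AT5G67000 (by 5.58-fold), LDOX (by 5.43-fold) and CHS (by 4.7-fold). AT4G25820, and GSTF2 named below, had saturated pixels on 4 of all 12 arrays each. In all, 988 genes rose and 1180 fell among 21244 tested. With shoots fitted alone 173 rose and 203 fell, and LDOX no longer passed (adjusted p = 0.0903, 5.48e-06 to 0.0903 over the alternatives). The total of 2168 was 1360 without replicate 3 of the ACD- shoots; without ACD+ shoot arrays it was 3729 (replicate 2) and 3380 (replicate 3), and without ACD+ root arrays 1436 (replicate 1) and 1443 (replicate 2).

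**Figure D1:**
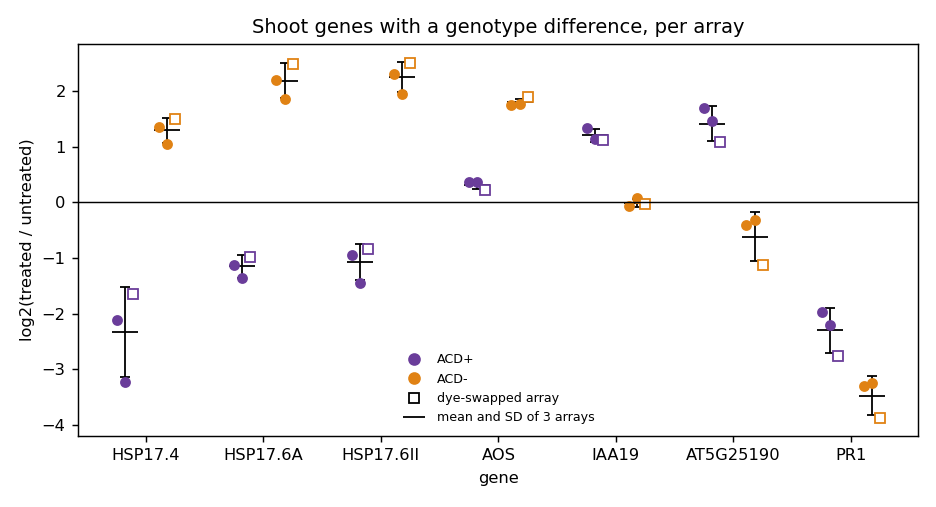
Log2 ratio of treated to untreated shoots on each array for 7 genes, with the mean and SD of 3 arrays per genotype. Open squares mark the dye-swapped array.

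Jasmonate genes rose as a group in ACD- shoots (mean log2 0.249, adjusted p = 0.000448; adjusted p = 0.0861 with an estimated correlation). Of 24 measured, 7 rose and 0 fell in limma over all genes, and 9 rose when adjusted over the list alone, among them AOS, the repressors JAZ3 (0.71), JAZ9 (0.58) and JAZ2 (0.47), and OPR3, which makes a jasmonate precursor (0.56). The call also ended without both dye-swapped shoot arrays (adjusted p = 0.409, 0.000222 to 0.409 over the alternatives). Heat shock genes rose (mean log2 0.663, adjusted p = 0.0238; adjusted p = 0.286 with an estimated correlation). Of 10 measured, 6 rose and 2 fell over all genes, and 6 and 3 when adjusted over the list alone. HSP17.4 (1.4 ± 0.19) and HSP21 (1.3) were among those that rose, and HSP101 (-0.30) and the regulator HSFA2 (-0.48) fell. Of 33 alternatives 7 ended the call, the authors' values among them (adjusted p = 0.124, 0.000575 to 0.409 over the alternatives). Phenylpropanoid genes fell (mean log2 -0.565, adjusted p = 1.3e-07; adjusted p = 0.125 with an estimated correlation). Of 22 measured, 11 fell over all genes, and 14 fell and 1 rose when adjusted over the list alone, among them CHS (-2.23 ± 0.12), LDOX (-2.44 ± 0.39), F3H (-1.09) and the anthocyanin regulator PAP1 (-0.89). Cell wall growth genes fell (mean log2 -0.305, adjusted p = 0.000116; adjusted p = 0.125 with an estimated correlation). Of 27 measured, 10 fell and 1 rose over all genes, and 12 and 1 when adjusted over the list alone, including TCH4 (-1.64), XTH20 (-1.61) and XTH15 (-0.98).

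Oxidative stress genes fell in ACD- shoots (mean log2 -0.318, adjusted p = 0.0279; adjusted p = 0.471 with an estimated correlation). GSTF7 (-1.78), GSTF2 (-1.52) and CSD1 (-1.05) were the 3 of 14 that fell (3 lower and 1 higher adjusted over the list alone), and 8 of 33 alternatives ended the call, such as leaving out replicate 2 of this group (adjusted p = 0.112, 0.00696 to 0.471 over the alternatives). Cytokinin genes fell (mean log2 -0.194, adjusted p = 0.0029; adjusted p = 0.286 with an estimated correlation). Of 15 measured, 4 fell (4 lower and 1 higher adjusted over the list alone), among them the cytokinin oxidase CKX6 (-0.76) and ARR8 (-0.44). The call also ended without both dye-swapped shoot arrays and without replicate 3 of this group (mean -0.077, adjusted p = 0.574 in the latter, 0.000704 to 0.864 over the alternatives). Of 17 ethylene biosynthesis genes ACO4 (2.28-fold, log2 1.19 ± 0.07) and ACO1 (0.55 ± 0.10) rose and ACS11 (-0.36) and ACS5 (-0.21) fell, with the same 2 and 2 adjusted over the list alone (mean 0.052, median -0.015 and test pointing down, adjusted p = 0.633). EIL1 (0.26) was the only 1 of 11 ethylene signalling genes to rise (adjusted p = 0.38). TEM1 (0.22) and RAP2.3 (0.22) rose and RAV1 (-0.29) fell of 16 ethylene responsive genes (adjusted p = 0.38). Both lists had the same numbers adjusted over the list alone. Without both dye-swapped shoot arrays the means of the ethylene signalling and responsive lists turned negative (-0.115 and -0.148).

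In the remaining lists of ACD- shoots, 6 of 26 salicylate and immunity genes fell and 1 rose (7 and 3 adjusted over the list alone; mean -0.199, median 0.022, adjusted p = 0.187), with PR2 (-1.05) and WRKY18 (-0.52) lower and RBOHD higher (0.38). Of 27 abscisate, drought and cold genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.699), with COR413PM1 (1.99-fold) and RD29A (0.95) higher. Auxin genes showed 2 lower of 38, GH3.5 (-0.34) among them (1 adjusted over the list alone; adjusted p = 0.187). Glucosinolate genes showed 1 higher, ESP (0.83), and 2 lower of 26, also adjusted over the list alone (mean -0.021, median 0.004, adjusted p = 0.679), and gibberellin genes 2 higher of 14, RGL1 (0.46) and GA2OX2 (0.29), also adjusted over the list alone (adjusted p = 0.308). Nitrogen genes showed 2 higher, GDH2 (0.78) and NRT1.1 (0.42), and 1 lower, AMT1;1 (-0.53), of 12 (2 and 2 adjusted over the list alone; adjusted p = 0.699). Photosynthesis had 1 lower of 56, RBCS2B (-0.44), also adjusted over the list alone (mean 0.003, with median and test pointing down, adjusted p = 0.873), and cell cycle 1 lower of 17, PCNA2 (-0.19) (0 adjusted over the list alone; adjusted p = 0.116). None of 17 root markers (adjusted p = 0.924) or 9 reference genes (adjusted p = 0.633) passed.

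The responses of shoots to ACD+ and ACD- bacteria overlapped. A difference in collection time between treated and untreated shoots could enter both responses and stays open as a source of overlap. TOC1, AT3G07650, ACO4 and ESP rose and CHS, PR1, GSTF7 and TCH4 fell with both. In all, 578 genes rose and 712 fell in both, where independent responses would give 121 and 137, and 132 moved in opposite directions, such as HSP17.6A and JAZ9. Across all probes the ACD+ and ACD- responses correlated at r = 0.433 with a covariance of 0.034. If both groups were compared with the same untreated RNA, 100 simulations without any effect, each tissue with its own spread, gave on average r = 0.543, a covariance of 0.0174 and an overlap of 78.3 higher and 78.1 lower genes (101 and 102 at most). With shoots fitted alone 271 genes were shared in place of 1290.

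The comparison of ACD+ with ACD- shoots tests the effect of the bacterial genotype in shoots. The clearest difference was in small heat shock proteins: HSP17.4 was lower with ACD+ than ACD- bacteria by 12.3-fold (log2 -3.62 ± 0.26, n = 3 per group), HSP17.6A by 10.1-fold (-3.33 ± 0.11) and HSP17.6II by 9.99-fold (-3.32 ± 0.13). A sti1-like co-chaperone gene (AT4G12400, by 5.55-fold), a glutathione transferase (AT2G29440, by 4.86-fold), a methyltransferase-related gene (AT3G44870, by 5.74-fold) and AOS (by 2.79-fold, -1.48 ± 0.08) were also lower. An ethylene-responsive element-like gene (AT5G25190) was higher by 4.09-fold (2.03 ± 0.09), as were the GPI-anchored protein gene AT4G28280 (2.88-fold), AT2G14580 (2.85-fold), IAA19 (2.3-fold, 1.2 ± 0.08) and PR1 (2.25-fold). The receptor kinase-like AT4G39270 (1.38 ± 0.33), the PREG-like AT5G61650 (1.38) and the F-box gene AT1G10780 (1.37 ± 0.32) were higher as well. Of 32 alternatives, 21 ended the call of AT4G39270 (adjusted p 0.00181 to 0.346), 11 that of AT5G61650 (0.00633 to 0.365) and 19 that of AT1G10780 (0.00607 to 0.514), which also turned to -0.142 with the authors' values.

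In total 759 genes were higher and 747 lower with ACD+ bacteria. With shoots fitted alone 3 were higher and 9 lower, among them AT5G25190, HSP17.6A, HSP17.6II, AT4G12400, AT2G29440 and AOS, and HSP17.4 (adjusted p = 0.0606, 4.96e-07 to 0.111 over the alternatives), IAA19 (0.0629, 6.4e-06 to 0.199) and PR1 (0.0629, 1.4e-05 to 0.199) no longer passed. With the number as a fixed replicate block and shoots alone, HSP17.6A and HSP17.6II alone remained (adjusted p = 0.0216 for both, the highest over their alternatives, the lowest being 3.4e-08 and 8.82e-08). With the block AT4G12400 (0.0808), AT2G29440 (0.0808), AT5G25190 (0.111), HSP17.4 (0.111), AOS (0.176), IAA19 (0.199) and PR1 (0.199) did not pass, these being the highest adjusted p-values over their alternatives; the lowest lay between 3.16e-08 for AT4G12400 and 1.4e-05 for PR1. No other gene passed with the block, the named ones ranging from 0.176 for AT2G14580 to 0.495 for AT1G10780. With that block and both tissues fitted together 1018 genes differed, 884 of them among the 1506, and AT5G61650 (0.0541) and AT1G10780 (0.13) were the only named ones that lost the call. The share of genes higher was 50.4% against 35% with ratios scaled between arrays (79 higher and 147 lower). The total of 1506 became 3908 without replicate 2 of the ACD+ shoots, 714, 715 and 729 without replicates 1, 2 and 3 of the ACD+ roots, and 916 and 729 without replicates 1 and 3 of the ACD- roots.

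Heat shock genes differed most as a group between ACD+ and ACD- shoots (mean log2 -1.361, adjusted p = 1.62e-08, 0.0317 with an estimated correlation), 6 of 10 lower over all genes, and 6 lower and 1 higher when adjusted over the list alone; HSP90.1 (by 2.49-fold) and HSP17.4 were among them. Auxin genes were higher (mean 0.339, adjusted p = 1.62e-08, 0.032 with an estimated correlation), 15 of 39 over all genes, and 19 higher and 1 lower when adjusted over the list alone, including IAA19, IAA2 (0.85), PIN3 (0.85), IAA3 (0.82), IAA29 (0.78) and AUX1 (0.60). Jasmonate genes were lower (mean -0.404, adjusted p = 9.04e-08, 0.0143 with an estimated correlation), 9 of 24 over all genes and 11 adjusted over the list alone, including AOS, JAZ9 (-1.12), CORI3 (-0.72), OPR3 (-0.68) and JAZ2 (-0.64). Glucosinolate genes were lower (mean -0.27, adjusted p = 0.000128, 0.0317 with an estimated correlation), 5 of 27 over all genes and 10 adjusted over the list alone, including NIT4 (-0.91) and CYP83B1 (-0.77). These 4 lists passed in every alternative, with the replicate block among them (heat shock mean -1.388, adjusted p = 6.47e-09, 3.22e-12 to 0.0317 over the alternatives).

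Cell wall growth genes were higher with ACD+ than ACD- bacteria in shoots (mean log2 0.234, adjusted p = 0.000545; adjusted p = 0.117 with an estimated correlation). Of 27, 7 were higher and 1 lower over all genes and 8 and 1 adjusted over the list alone, including XTH18 (0.89), EXPA15 (0.71) and XTH4 (0.54). Phenylpropanoid genes were lower (mean -0.234, adjusted p = 0.00195; adjusted p = 0.299 with an estimated correlation), 2 of 22 over all genes, COMT1 (-1.18) and FLS1 (-0.78), and 8 adjusted over the list alone. The call also ended with scaled ratios (adjusted p = 0.0966, 2.83e-05 to 0.299 over the alternatives). Nitrogen genes were lower (mean -0.301, adjusted p = 0.0198; adjusted p = 0.459 with an estimated correlation). Of 12, 3 were lower and 1 higher over all genes and 4 and 1 adjusted over the list alone, with GLN1;1 (-1.0) and NIA1 (-0.64) lower. Of 35 alternatives 10 ended the call, such as leaving out replicate 1 of the ACD+ shoots (adjusted p = 0.106, 0.000928 to 0.459 over the alternatives). Ethylene responsive genes were lower (mean -0.171, adjusted p = 0.0198; adjusted p = 0.339 with an estimated correlation). TEM1 (-0.45) was the only 1 of 16 to pass over all genes, and 3 did adjusted over the list alone. Of 35 alternatives 9 ended the call, such as leaving out replicate 3 of the ACD+ shoots (adjusted p = 0.138, 0.00635 to 0.339 over the alternatives). Of 18 ethylene biosynthesis genes ACO5 (2.46-fold, 1.3 ± 0.19), ACS5 (0.84) and ACS8 (0.79) were higher (5 higher and 2 lower adjusted over the list alone; mean 0.136, adjusted p = 0.157), while ACO1 (-0.52) did not pass (adjusted p = 0.0535), though it did in 5 of 33 alternatives (0.0108 to 0.454). ACO5 had saturated pixels on 4 of all 12 arrays. EIL1 (0.36) and EIN3 (0.28) were the 2 of 11 ethylene signalling genes that were higher, also adjusted over the list alone (adjusted p = 0.247). With the fixed replicate block ACO5 (adjusted p = 0.199, 0.000974 to 0.199 over the alternatives) and ACS5 (0.249, 0.000198 to 0.249) did not pass.

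The other lists did not differ between ACD+ and ACD- shoots. Among their members, RD29A (-0.89), PYK10 (-1.0) and RBOHD (-0.47) were lower and ARR16 (0.81), CKX6 (0.47), PR1 (1.17) and RBCS2B (0.71) higher. PYK10 had saturated pixels on 6 arrays. Adjusted p-values were 0.314 for abscisate, drought and cold, 0.321 for cell cycle, 0.394 for cytokinin (mean 0.078, median -0.002), 0.273 for gibberellin, 0.239 for oxidative stress, 0.571 for photosynthesis (mean -0.043, median 0.004), 0.148 for reference genes, 0.387 for root markers and 0.981 for salicylate and immunity.

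Of the root responses, that to ACD+ bacteria comes first. A glutaredoxin gene (AT1G28480) fell by 2.07-fold (log2 -1.05 ± 0.07, n = 3), the jasmonate repressor JAZ2 by 2.06-fold (-1.04 ± 0.11), the light-harvesting gene LHCB1.2 by 1.91-fold (-0.93 ± 0.14), a putative hydrolase (AT2G32150) by 1.84-fold and OPR3 of jasmonate synthesis by 1.83-fold (-0.87 ± 0.07). A beta-amylase (AT5G18670, by 1.7-fold) and AOS (by 1.58-fold) fell too, as did WRKY40 (-0.66), CSD1 (-0.53) and the cytokinin response regulator ARR5 (-0.51). An ERD6-like sugar transporter (AT1G08900) was the only gene to rise (1.38-fold, 0.46 ± 0.07, adjusted p = 0.0494). Of 32 alternatives 18 ended that call (adjusted p 5.42e-06 to 1), 15 that of CSD1 (3.32e-06 to 1), 14 that of LHCB1.2 (1.97e-06 to 1), 13 that of ARR5 (1.83e-06 to 1) and 11 that of AT5G18670 (8.41e-07 to 1), and of 31 alternatives 16 ended that of WRKY40 (2.29e-06 to 1). JAZ2 lost its call in 6, AOS in 5 and AT2G32150 in 4 of 32. In all 63 genes fell and 1 rose among 21500; with roots fitted alone 867 fell and 99 rose. The total of 64 became 0 without any of the 3 ACD+ root arrays, 163, 6 and 3 without ACD- root replicates 2, 1 and 3, 18 and 140 without ACD+ shoot replicates 1 and 2, and 4 and 10 without ACD- shoot replicates 1 and 2. The share of genes higher, 1.56%, was 23.7% with scaled ratios (1183 higher and 3815 lower) and 39.3% with array weights. LHCB1.2 had saturated pixels on 6 arrays, and AT5G54770 and ACO5, named below, on 6 and 4.

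Jasmonate genes fell in ACD+ roots (mean log2 -0.173, adjusted p = 0.00462; adjusted p = 0.125 with an estimated correlation): JAZ2, OPR3 and AOS, 3 of 24, fell over all genes and 7 when adjusted over the list alone. Of 33 alternatives 5 ended the call, roots fitted alone among them (adjusted p = 0.0786, 0.000812 to 0.125 over the alternatives). No ethylene gene passed over all genes: the adjusted p was 0.823 for 18 ethylene biosynthesis genes (mean -0.012, with median and test pointing up), 0.291 for 11 signalling genes and 0.696 for 16 responsive genes, of which 1 fell when adjusted over the list alone. ACO1 (0.10) and ACO5 (-0.22) marked the range of the biosynthesis genes, and NIA1 (0.40), the thiazole synthesis gene AT5G54770 (0.41) and the sugar transporters AT2G48020 (0.32) and AT5G18840 (0.32) had the next smallest p-values among the higher genes with a product name, without passing. In some alternatives they passed: AT5G54770 and AT2G48020 in 7 of 32, NIA1 and AT5G18840 in 5, and ACO5 in 2. Of the other lists none passed: photosynthesis (1 of 57 lower, adjusted p = 0.087), cell wall growth (adjusted p = 0.138), auxin (0.291), cytokinin (1 of 15 lower, 0.565), phenylpropanoid (0.683), glucosinolate (0.696), nitrogen (0.696), cell cycle (0.696), root markers (0.696), oxidative stress (1 of 15 lower, 0.734), abscisate, drought and cold (0.734), salicylate and immunity (1 of 26 lower, 0.734), reference genes (0.877), gibberellin (0.908) and heat shock (0.968).

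**Figure D2:**
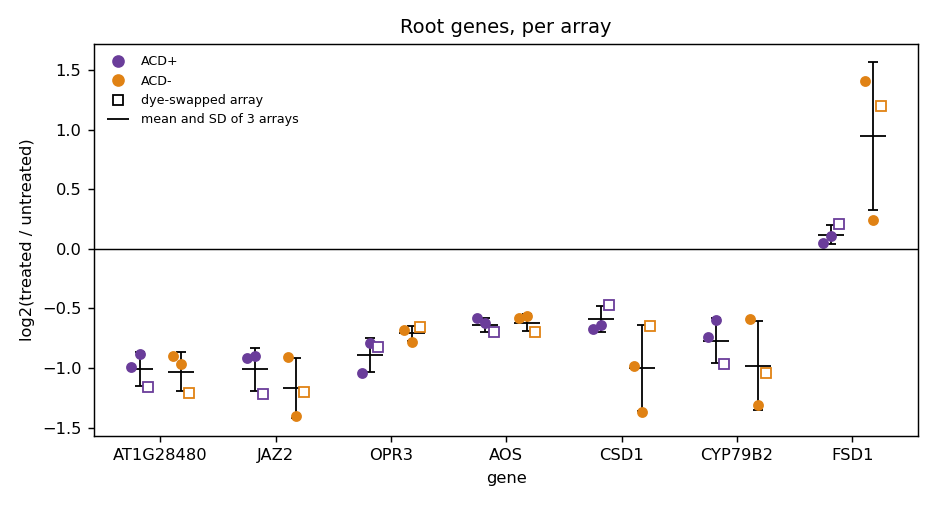
Log2 ratio of treated to untreated roots on each array for 7 genes, with the mean and SD of 3 arrays per genotype. Open squares mark the dye-swapped array.

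The response of roots to ACD- bacteria follows. JAZ2 fell by 2.3-fold (log2 -1.20 ± 0.11, n = 3), AT1G28480 by 2.1-fold (-1.07 ± 0.07), LHCB1.2 by 2.03-fold, CYP79B2, which makes an indole glucosinolate precursor, by 2.02-fold (-1.01 ± 0.13), a ferredoxin NADP oxidoreductase (AT1G30510) by 1.96-fold and CSD1 by 1.92-fold (-0.94 ± 0.08). CYP79B3 (by 1.75-fold), OPR3 (by 1.62-fold) and AOS (by 1.55-fold) fell too. The iron superoxide dismutase FSD1 was the only gene to rise (1.99-fold, 0.99 ± 0.19, adjusted p = 0.0354), while carbonic anhydrase CA1 (1.12 ± 0.24) and a dehydrogenase gene (AT5G62530, 0.21) did not pass. Of 32 alternatives 14 ended the call of AT1G30510 (adjusted p 0.00065 to 0.53), 10 that of FSD1 (2.91e-05 to 0.557), 5 that of CYP79B2 (1.82e-05 to 0.499) and 4 that of LHCB1.2 (1.29e-05 to 0.499). Of the list members named below, PCNA2 lost its call in 8, IAA17 and CESA6 in 7, ABF3 and XTH9 in 6 and CYP83B1 in 5. Conversely CA1 passed in 14 (1.92e-05 to 0.726) and AT5G62530 in 8 (0.000213 to 0.776). In all 570 genes fell and 1 rose among 21500, and with roots fitted alone 2945 fell and 1389 rose. The total of 571 became 0 and 19 without ACD- root replicates 3 and 2, 17, 8 and 8 without ACD+ root replicates 1, 2 and 3, 196 without ACD- shoot replicate 1 and 1087 without ACD+ shoot replicate 2. Saturated pixels were present for LHCB1.2 and AT5G54770 on 6 arrays, CA1 on 5, ACO5 on 4 and AT1G30510 on 3. The share of genes higher, 0.175%, was 21% with scaled ratios (1029 higher and 3865 lower) and 33% with array weights.

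Jasmonate genes fell in ACD- roots (mean log2 -0.206, adjusted p = 0.00497; adjusted p = 0.161 with an estimated correlation), 6 of 24 by both adjustments, over all genes and adjusted over the list alone: JAZ2, OPR3, the cyclase AOC3 (-0.68), AOS, JAZ9 (-0.36) and the transcription factor MYC2 (-0.33). Cell wall growth genes fell (mean -0.172, adjusted p = 0.00497; adjusted p = 0.39 with an estimated correlation), 2 of 27 over all genes, the cellulose synthase CESA6 (-0.48) and XTH9 (-0.43), and 9 lower and 1 higher when adjusted over the list alone. The call also ended with the stricter intensity filter (adjusted p = 0.142, 0.00138 to 0.39 over the alternatives). No ethylene gene passed over all genes (adjusted p = 0.56 for biosynthesis, mean -0.025 with median and test pointing up, 0.307 for signalling and 0.307 for responsive genes, of which 1 fell adjusted over the list alone); ACS6 (0.12) and ACO5 (-0.55) marked the range of the biosynthesis genes. In 9 of 32 alternatives ACO5 passed (adjusted p 0.00176 to 0.697), and in 2 ACS6 did (0.021 to 1).

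Of the lists that did not pass in ACD- roots, auxin had 4 of 39 lower, among them IAA17 (-0.63), PIN3 (-0.46) and IAA3 (-0.43) (7 adjusted over the list alone; adjusted p = 0.307), and glucosinolate 3 of 27, CYP79B2, CYP79B3 and CYP83B1 (-0.49), also adjusted over the list alone (adjusted p = 0.307). Photosynthesis had 3 of 57 lower, including LHCB1.2 and PSBW (-0.44) (9 lower and 1 higher adjusted over the list alone; adjusted p = 0.307), and oxidative stress FSD1 higher and 3 of 15 lower, CSD1, GSTU19 (-0.54) and GSTF8 (-0.39) (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.125). WRKY40 (-0.76) and WRKY33 (-0.51) fell of 26 salicylate and immunity genes (4 adjusted over the list alone; adjusted p = 0.946). ABF3 (-0.59) and RAB18 (-0.48) fell of 28 abscisate, drought and cold genes (3 adjusted over the list alone; adjusted p = 0.105), and GDH1 (-0.56) and GLN2 (-0.40) of 12 nitrogen genes, also adjusted over the list alone (adjusted p = 0.125). ARR8 (-0.34), PCNA2 (-0.34) and PHT1;1 (-0.41) were the single members that fell of the cytokinin (adjusted p = 0.451), cell cycle (0.56) and root marker lists (0.315). No gibberellin (adjusted p = 0.628), heat shock (0.946), phenylpropanoid (0.56) or reference gene (0.451) passed.

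The root responses to ACD+ and ACD- bacteria overlapped in 58 genes that fell in both, JAZ2, OPR3, AOS, AT1G28480 and CSD1 among them, where independent responses would give 1.67. The responses correlated at r = 0.835 with a covariance of 0.0142. Simulations without effect, with shared untreated RNA and the spread of each tissue, gave r = 0.544, a covariance of 0.00193 and 0.02 shared lower genes on average. With roots fitted alone 801 genes were shared.

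The comparison of ACD+ with ACD- roots tests the effect of the bacterial genotype in roots. No gene differed (0 of 21500 in limma; 143 had an unadjusted p under 0.05), and none did with roots fitted alone (1375 unadjusted) or with the fixed replicate block (1092 unadjusted). The genes with a product name and the smallest p in either direction were a family 18 glycosyl hydrolase (AT4G19760, log2 0.82 ± 0.14), NIA1 (0.60 ± 0.13), a heat shock gene (AT1G56410, 0.56), the calcium-binding AT5G39670 (0.41), AT5G40850 (0.34), CA1 (-1.01), FSD1 (-0.83 ± 0.26), the iron transporter AT4G19680 (-0.47), AT4G38810 (-0.34) and AT1G30760 (-0.25), all with an adjusted p of 1. ACO5 (0.33) and ACS8 (-0.12) marked the range of the ethylene biosynthesis genes. CA1 had saturated pixels on 5 arrays and ACO5 on 4. Array weights gave 49 genes that differed.

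As groups, cell wall growth genes (mean log2 0.086, adjusted p = 0.00343; adjusted p = 0.412 with an estimated correlation), oxidative stress genes (0.064, adjusted p = 0.00343; adjusted p = 0.417 with an estimated correlation) and abscisate, drought and cold genes (0.061, adjusted p = 0.00628; adjusted p = 0.412 with an estimated correlation) were slightly higher with ACD+ than ACD- bacteria in roots. Of their members 0 passed in limma over all genes or adjusted over the list alone. All 3 calls ended with the fixed replicate block in roots alone (adjusted p = 0.0511 for each) and with roots fitted alone (0.0779, 0.0766 and 0.074), but passed with that block and both tissues together (0.00403, 0.00668 and 0.0123). Over the alternatives the adjusted p ran from 0.000999 to 0.412, 0.000452 to 0.467 and 0.00219 to 0.412, and the oxidative stress mean turned to -0.006 with the authors' values. The ethylene lists did not differ: biosynthesis 0.013 (median -0.01 and test pointing down, adjusted p = 0.727), signalling 0.008 (median -0.003 and test pointing down, adjusted p = 0.906) and responsive 0.042 (adjusted p = 0.48). The remaining lists did not pass either, the lowest adjusted p-values being those of phenylpropanoid (0.0801) and reference genes (0.126).

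**Figure D3:**
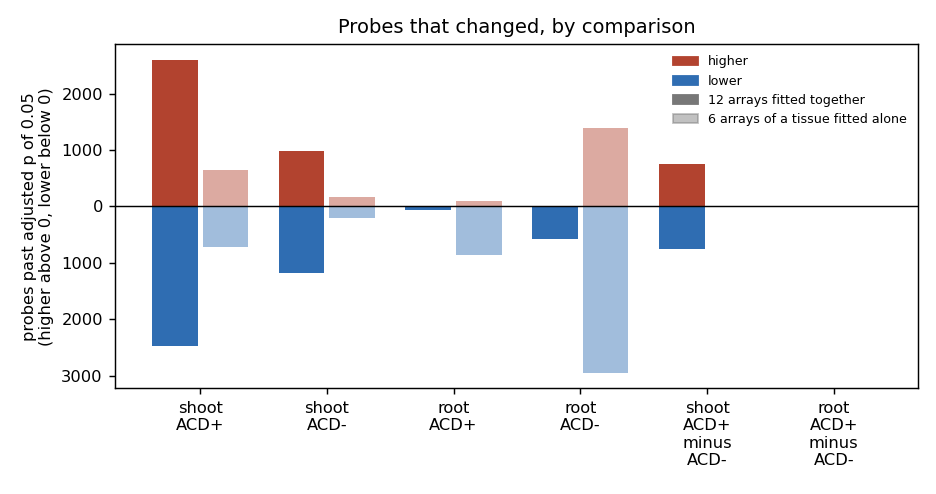
Genes higher (above 0) and lower (below 0) past an adjusted p of 0.05 in 6 comparisons. Dark bars are from all 12 arrays fitted together and pale bars from each tissue fitted alone.

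The root responses were also set against the shoot responses, where tissue and scan period cannot be told apart. For ACD+ bacteria phenylpropanoid genes responded more positively in roots than in shoots (mean log2 difference 0.806, adjusted p = 3.22e-09; adjusted p = 0.0837 with an estimated correlation). Of 22, 12 were higher over all genes and 15 adjusted over the list alone. Heat shock genes did likewise (0.69, adjusted p = 3.72e-06; adjusted p = 0.0837 with an estimated correlation), 5 of 10 higher and 1 lower over all genes and 6 and 1 adjusted over the list alone. Oxidative stress genes (0.457, adjusted p = 0.00243; adjusted p = 0.261 with an estimated correlation) had 3 of 14 higher by both adjustments, over all genes and adjusted over the list alone, and glucosinolate genes (0.205, adjusted p = 0.00233; adjusted p = 0.0837 with an estimated correlation) 7 of 26 higher and 1 lower, likewise by both. Auxin genes responded more negatively in roots (-0.34, adjusted p = 1.25e-05; adjusted p = 0.0908 with an estimated correlation), 17 of 38 lower and 1 higher over all genes and 19 and 1 adjusted over the list alone. The glucosinolate and oxidative stress calls also ended with scaled ratios (adjusted p = 0.233 and 0.411, with 0.000584 to 0.233 and 0.000553 to 0.411 over the alternatives). The heat shock call also ended with the authors' values (adjusted p = 0.0897, 9.47e-08 to 0.0897 over the alternatives). In all 1272 genes were more positive and 1956 more negative in roots; the total of 3228 became 1468, 1590 and 548 without ACD+ root replicates 1, 2 and 3, 2119 without ACD- root replicate 3 and 5512 without ACD+ shoot replicate 2.

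For ACD- bacteria jasmonate genes responded more negatively in roots than in shoots (mean log2 difference -0.455, adjusted p = 3.09e-05, 0.0397 with an estimated correlation), 7 of 24 lower over all genes and 11 adjusted over the list alone; AOS rose in shoots (1.79) and fell in roots (-0.64). Phenylpropanoid genes responded more positively (0.505, adjusted p = 3.09e-05; adjusted p = 0.383 with an estimated correlation), 10 of 22 higher over all genes and 11 adjusted over the list alone. Their mean was -0.06 in roots, against -0.565 in shoots. The jasmonate call ended without both dye-swapped shoot arrays (adjusted p = 0.209, 8.65e-06 to 0.209 over the alternatives). In all 557 genes were more positive and 1053 more negative in roots; tissue and scan period cannot be told apart here either. The total of 1610 became 157 and 708 without ACD- root replicates 3 and 2, 759, 758 and 697 without ACD+ root replicates 1, 2 and 3, and 3119 and 2580 without ACD+ shoot replicates 2 and 3.

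The genotype difference itself differed between tissues for 184 genes, 116 more positive and 68 more negative in roots. Heat shock genes led (mean log2 1.401, adjusted p = 4.38e-10, 0.0192 with an estimated correlation), 6 of 10 more positive over all genes and 6 positive and 1 negative adjusted over the list alone. Jasmonate genes (0.437, adjusted p = 3.18e-08, 0.0121 with an estimated correlation; 3 of 24, and 10 adjusted over the list alone) and glucosinolate genes (0.323, adjusted p = 6.86e-05, 0.0192 with an estimated correlation; 3 of 27, and 6 adjusted over the list alone) were more positive, and auxin genes more negative (-0.311, adjusted p = 1.3e-08, 0.032 with an estimated correlation; 4 of 39, and 15 adjusted over the list alone). Phenylpropanoid (0.301, adjusted p = 0.000367; adjusted p = 0.242 with an estimated correlation), nitrogen (0.387, adjusted p = 0.0121; adjusted p = 0.377 with an estimated correlation), oxidative stress (0.248, adjusted p = 0.0209; adjusted p = 0.352 with an estimated correlation), ethylene responsive (0.213, adjusted p = 0.0121; adjusted p = 0.298 with an estimated correlation) and cell wall growth genes (-0.148, adjusted p = 0.0145; adjusted p = 0.242 with an estimated correlation) also passed. Of 33 alternatives, 10 ended the nitrogen call (adjusted p 0.000189 to 0.377), 8 the oxidative stress call (0.00365 to 0.352), 7 the ethylene responsive call (0.00436 to 0.298) and 4 the cell wall growth call (0.000101 to 0.242), the estimated correlation among them. With the fixed replicate block and both tissues fitted together 67 genes passed, 65 of them among the 184. The total of 184 became 1 with the authors' values and 1 with the misplaced file averaged in, and 26 with scaled ratios (73.1% more positive against 63%). It was 544 and 1217 without ACD+ shoot replicates 1 and 2, 39, 34 and 32 without ACD+ root replicates 1, 2 and 3, and 70, 84 and 32 without ACD- root replicates 1, 2 and 3. Tissue and scan period cannot be told apart in these values.

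**Figure D4:**
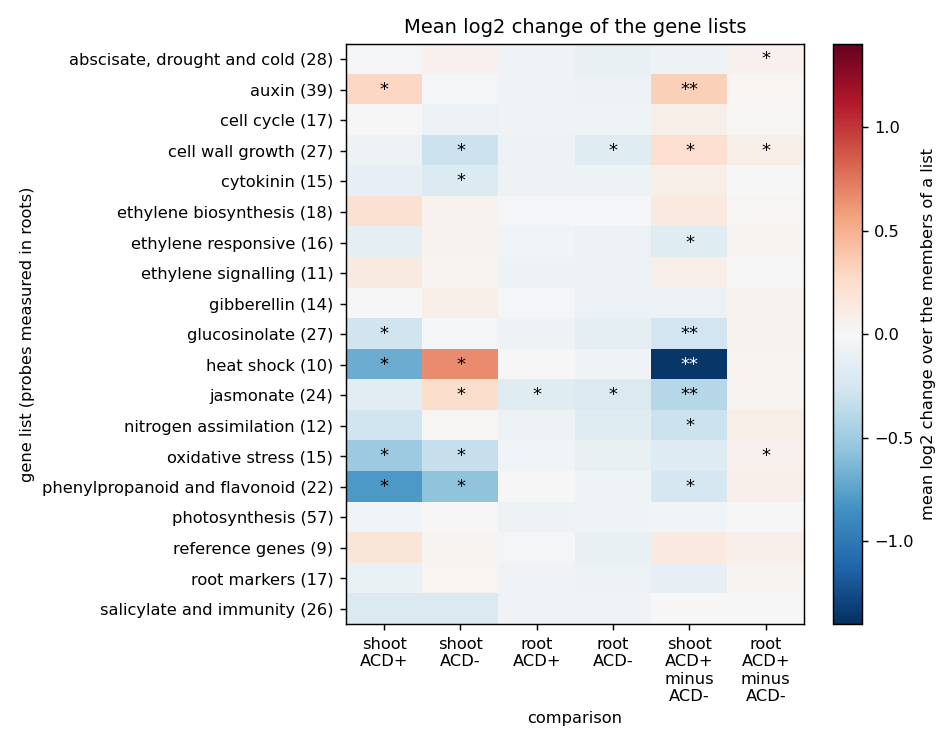
Mean log2 change of 19 gene lists in 6 comparisons. An asterisk marks camera adjusted p under 0.05, and 2 asterisks that it also holds with an estimated correlation.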

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

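Chosen only after the result was seen were the tests of dye bias, the later of the 2 tests of dye orientation, the 5 tests on the root counts, the splits that part every same-numbered pair, and the fixed replicate block with both tissues fitted together; the earlier test of dye orientation, the tests on times of day and the counts over other splits of the arrays were written before.

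Responses that differed between tissues stood out, by a test of the difference itself; tissue and scan period cannot be told apart in any of them. For ACD+ bacteria 3228 genes differed between roots and shoots. Among lists, auxin genes (mean log2 difference -0.34) were more negative in roots, and glucosinolate (0.205), heat shock (0.69), oxidative stress (0.457) and phenylpropanoid and flavonoid genes (0.806) more positive. None of these 5 calls held with an estimated correlation: adjusted p = 0.0908, 0.0837, 0.0837, 0.261 and 0.0837 with an estimated correlation. For ACD- bacteria 1610 genes differed, with jasmonate genes more negative (-0.455) and phenylpropanoid genes more positive (0.505; adjusted p = 0.383 with an estimated correlation) in roots. Of the 10 splits of the 6 arrays into equal groups only the real one reached either count, and the highest other gave 0 in both, but 10 splits are too few for a share under 0.05.

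The genotype difference also differed between tissues, for 184 genes and 9 lists: auxin (mean log2 -0.311) and cell wall growth (-0.148) more negative in roots, and ethylene responsive (0.213), glucosinolate (0.323), heat shock (1.401), jasmonate (0.437), nitrogen assimilation (0.387), oxidative stress (0.248) and phenylpropanoid genes (0.301) more positive. Of these, 5 calls were lost: adjusted p = 0.242 with an estimated correlation for cell wall growth and for phenylpropanoid, 0.298 for ethylene responsive, 0.377 for nitrogen and 0.352 for oxidative stress genes. Of 100 drawn splits 3 gave as many genes as the real 184, the real one included, a share under 0.05. These splits ignored that same-numbered arrays share a dye orientation and deviated together before the dye was removed. Of the 32 splits that part every pair, as the real one does, 2 gave as many (highest other 200), so that chance is not excluded once the pairs are kept. The highest of all splits, 461, left some pairs together, so the arrays have a structure beyond their groups. With the fixed replicate block and both tissues fitted together the count was 67. Of the genes named in the report, the response differed between tissues for 26 in ACD+ shoots, 21 in ACD- shoots, 8 in ACD+ roots and 13 in ACD- roots; the genotype difference differed between tissues for 18 genes named in shoots and 4 named in roots.

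For the responses themselves, 1 of 4 splits of the signs of the 3 arrays, the real one, gave as many genes: 5072 in ACD+ shoots (highest other 665), 2168 in ACD- shoots (41), 64 in ACD+ roots (0) and 571 in ACD- roots (0). For the genotype difference 1 of 10 splits gave the 1506 of shoots (highest other 838), and 10 of 10 gave the 0 of roots (highest other 119). Among the 4 splits that part every same-numbered pair the highest other gave 71 in shoots and 0 in roots, so the 838 and 119 came from splits that left pairs together. With the fixed replicate block 2 shoot genes remained with shoots alone and 1018 with both tissues fitted together. These splits are too few for a share under 0.05.

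Clock genes moved in treated shoots with both genotypes. Over clock genes not seen beforehand, evening genes exceeded morning genes by a median log2 of 1.33 in ACD+ and 1.19 in ACD- shoots, and by 0.23 and 0.24 in roots. The tables argue against a probe-specific dye bias, since that difference over the genes not seen beforehand was at least 1.08 on every shoot array in both dye orientations. Open as candidate explanations are collection of treated and untreated shoots at different times of day (1.19 in the genotype with the smaller value) and the same for whole seedlings (0.23 in roots); the tests written for both came out as those explanations predict. A treatment effect on the clock was not tested and stays open.

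The dye-swapped shoot arrays differed from their unswapped partners. The tables argue against a wrong dye orientation in their labels: in the labelled orientation the evening minus morning difference was 1.3 on the array with the smaller value. An earlier test of the same explanation, written before, left it undecided, with mean correlations to the unswapped arrays, dye effects removed, of 0.16 in ACD+ and -0.0397 in ACD- shoots. A probe-specific dye bias may be a source, as dye effects of shoot and root arrays correlated at r = 0.436 and 2548 probes had a dye effect in shoots fitted alone and 2023 in roots fitted alone (8318 and 4 in the joint fit, with its shared spread). Replicate 3 was the only swapped array of each group, so dye effects cannot be told apart from anything else particular to it. No biological explanation was tested.

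Roots had few calls, mostly lower, and no genotype difference. The tables argue against shoot tissue in the untreated root samples for the falls at large, because photosynthesis probes changed by a median log2 of only -0.048 in the genotype with the lower value; for LHCB1.2, lower by 1.91- and 2.03-fold, and the 9 photosynthesis genes lower against 1 higher adjusted over the list alone in ACD- roots, it stays open. They also argue against a spread estimate shared with shoots as the source of the missing genotype difference, and as the only source of the direction. Fitted alone, 867 genes fell and 99 rose in ACD+ roots, 68% of calls in ACD- roots were lower, and 0 genes differed by genotype in limma (1375 unadjusted). For the number of calls the shared spread stays open as a candidate explanation, with 4334 genes in ACD- roots fitted alone against 571, as do compressed ratios on the root arrays (SD of dye effects in roots over shoots 0.316) and, untested, a weaker effect of the bacteria on roots.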

How the results depend on the processing

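The 4 alternatives added later were chosen only after results were seen. Of 101 called named genes, 46 kept direction and call in every alternative, and over 3054 alternative results 2743 stayed the same, 310 lost the call and 1 reversed. Of 41 called lists 8 kept both throughout, the estimated correlation included; of 1286 results 1169 stayed the same, 115 lost the call and 2 reversed. Signal over the negative controls of 2.02 to 6.13 limits faint genes in shoots; a filter on it raised root counts. Unless stated the cause was not tested. Keeping spots marked by the scanner moved no count by over 1.5 times. The background filter removed no probe and quantile scaling of mean intensities leaves log ratios as they are, so both alternatives test nothing; these totals leave them out, while counts of alternatives for single results include them. Averaging probes of a locus was not run.

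ACD+ shoots, 5072 genes: 3172 without dye term, 1364 with each tissue alone, 2253 with scaled ratios, 9845 without both swapped shoot arrays, 2904 to 7066 leaving out single arrays, 7716 unadjusted, 1210 with fold over 1.5. ACD- shoots, 2168: 1096 without dye term, 376 alone, 1173 scaled, 1086 with array weights, 3890 with the authors' values, 3297 with the misplaced file, 6829 without swapped arrays, 1360 to 3729 leaving out single arrays, 5036 unadjusted, 573 with fold over 1.5. Tissues fitted alone have fewer residual degrees of freedom and their own spread (0.181 in shoots, 0.0601 in roots, against 0.148). Array weights ran from 0.0898 to 6.51.

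ACD+ roots, 64 genes: 3 without dye term, 28 with 1 dye term, 966 alone, 383 without background correction, 34 with offset 0, 156 with background subtracted, 4998 scaled, 340 with the stricter filter, 7 with the first file only, 8749 with array weights, 371 with the authors' values, 183 with trended spread, 129 with the misplaced file, 130 above negative controls, 0 to 163 leaving out single arrays, 1950 unadjusted, 16 with fold over 1.5, 160 at adjusted p under 0.1. ACD- roots, 571: in the same order 84, 291, 4334 and 1377, then 863 with median centring, 4894 scaled, 1854 stricter, 370 first file, 6905 weights, 118 authors, 1186 trended, 1013 misplaced, 1117 above negative controls, 0 to 1087 leaving out single arrays, 3311 unadjusted, 98 with fold over 1.5, 1416 under 0.1.

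Genotype difference in shoots, 1506 genes: 335 without dye term, 656 with 1 dye term, 12 alone, 226 scaled, 3421 weights, 926 authors, 808 misplaced, 714 to 3908 leaving out single arrays, 4999 unadjusted, 724 with fold over 1.5, 2641 under 0.1, and 2 with the fixed replicate block with shoots alone, but 1018 with that block and both tissues fitted together. In roots, 0: 1 scaled, 49 weights, 143 unadjusted, and 0 leaving out any array. The fixed replicate block was run for the genotype comparisons only. With each tissue alone it kept all shoot list calls and ended the 3 root list calls, and over 53 genes and lists it ended 25 calls. With both tissues together it kept all list calls, and over 64 genes and lists it ended the calls of AT5G61650 and AT1G10780 in shoots. A random replicate block (consensus correlation -0.195) moved no count by over 1.5 times and changed 2 of 192 other results. Within the results each replicate block was run for, it changed no other call.

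Roots against shoots, ACD+, 3228 genes: 1615 without dye term, 5127 scaled, 5794 weights, 7930 without swapped arrays, 548 to 5512 leaving out single arrays, 6365 unadjusted, 1352 with fold over 1.5. ACD-, 1610: 585 without dye term, 2688 without background correction, 4049 scaled, 2708 stricter, 2581 misplaced, 6051 without swapped arrays, 157 to 3119 leaving out single arrays, 5112 unadjusted, 665 with fold over 1.5, 2954 under 0.1. Genotype by tissue, 184: 48 without dye term, 74 with 1 dye term, 322 without and 330 with subtracted background, 26 scaled, 278 stricter, 118 first file, 2888 weights, 1 authors, 1 misplaced, 67 with the fixed replicate block and both tissues together, 32 to 1217 leaving out single arrays, 2793 unadjusted, 414 under 0.1.

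Overlap in shoots, 1290: 758 without dye term, 271 alone, 679 scaled, 706 weights, 2324 authors, 5015 without swapped arrays, 923 to 1726 leaving out single arrays. Overlap in roots, 58: 3 without dye term, 25 with 1 dye term, 801 alone, 336 without background correction, 33 offset 0, 136 subtracted, 3331 scaled, 313 stricter, 7 first file, 5108 weights, 101 authors, 166 trended, 118 misplaced, 118 above negative controls, 0 to 130 leaving out single arrays. Replicate agreement in ACD- roots, 0.435, was 0.201 with the authors' values, which lack 1 array. With an estimated correlation, list calls went from 5 to 0 in ACD+ shoots, 6 to 0 in ACD- shoots, 1 to 0 and 2 to 0 in ACD+ and ACD- roots, 8 to 4 and 3 to 0 for the genotype difference in shoots and roots, 5 to 0 and 2 to 1 for roots against shoots with ACD+ and ACD-, and 9 to 4 for genotype by tissue.

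These means changed sign. In ACD- shoots, ethylene responsive (0.046) became -0.008 without dye term and -0.148 without swapped arrays (-0.036 to 0.084 leaving out single arrays), ethylene signalling (0.04) -0.007 and -0.115, and ethylene biosynthesis (0.052) -0.07 to 0.063 leaving out single arrays. In ACD+ shoots ethylene signalling (0.126) became -0.001 without swapped arrays. In ACD- roots ethylene biosynthesis (-0.025) became 0.009 with the authors' values (-0.051 to 0.004 leaving out single arrays). In the root genotype difference ethylene signalling (0.008) became -0.002 without background correction, -0.001 subtracted, -0.037 scaled, 0 with array weights and -0.01 with the authors' values (-0.006 to 0.018 leaving out single arrays); ethylene biosynthesis (0.013) -0.002 with weights and -0.014 with the authors' values (-0.02 to 0.043). There, with the authors' values, ethylene responsive (0.042) became -0.006 (-0.006 to 0.074 leaving out single arrays), oxidative stress (0.064) -0.006 (-0.028 to 0.135), and ACO5 (0.33) -0.005. In roots against shoots, ethylene responsive became -0.025 scaled with ACD+ (0.083) and 0.064 without swapped arrays with ACD- (-0.13); with ACD- ethylene signalling (-0.119) became 0.035 without swapped arrays, and ethylene biosynthesis (-0.083) ran from -0.111 to 0.035 leaving out single arrays. AT1G10780 (1.37 in the shoot genotype difference) became -0.142 with the authors' values.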

Other observations

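The families, the clock genes and the tests in this part were chosen only after the data were seen. Of 32 families formed from product names, proteasome genes, which degrade marked proteins, moved apart in the 2 tissues. In ACD+ shoots 23 of 51 rose and 1 fell (mean log2 0.189, adjusted p = 1.05e-06; adjusted p = 0.148 with an estimated correlation), and in ACD- shoots 4 rose (0.113, adjusted p = 0.00109; adjusted p = 0.398 with an estimated correlation). In ACD- roots 9 of 52 fell (-0.173, adjusted p = 1.26e-08; adjusted p = 0.145 with an estimated correlation), and in ACD+ roots the mean was -0.116 (adjusted p = 1.5e-06; adjusted p = 0.277 with an estimated correlation) with 0 members past 0.05 in limma. The difference between tissues was itself tested for ACD+ bacteria (mean -0.305, adjusted p = 2.02e-08; adjusted p = 0.184 with an estimated correlation; 24 of 51 lower and 1 higher); tissue and scan period cannot be told apart.

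Ribosomal protein genes, which build the translation machinery, rose in ACD+ shoots for 39 of 290 and fell for 5 (mean log2 0.105, adjusted p = 0.00485; adjusted p = 0.616 with an estimated correlation), and fell for 18 and rose for 3 in ACD- shoots (-0.109, adjusted p = 0.00109; adjusted p = 0.545 with an estimated correlation). The genotype difference in shoots was 0.21 (adjusted p = 7.99e-09; adjusted p = 0.494 with an estimated correlation), with 18 of 292 higher. In ACD- roots 41 of 292 fell (-0.191, adjusted p = 9.02e-09; adjusted p = 0.279 with an estimated correlation). Cytochrome P450 genes, which act in secondary metabolism, fell for 46 of 233 and rose for 11 in ACD+ shoots (-0.123, adjusted p = 0.0012; adjusted p = 0.059 with an estimated correlation). Tubulin genes of the cytoskeleton rose there for 8 of 21 and fell for 1 (0.27, adjusted p = 0.0012; adjusted p = 0.27 with an estimated correlation). The directions of the family means given here held in 6 alternatives of background, scaling, filter and the authors' values.

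Among clock genes, the morning genes RVE8 (-1.5 in ACD+ and -1.01 in ACD- shoots), LNK2 (-1.84 and -0.99), LHY (-0.93 and -0.89) and PRR9 (-0.52 and -0.36) fell in shoots with both genotypes, while RVE1 (-0.17 and -0.46) and LNK1 (-0.2 and -0.3) did not pass. The evening genes LUX (1.25 and 1.83), PRR5 (1.22 and 1.19) and GI (0.6 and 0.6) rose with both, and CCR2 (1.09), ELF3 (0.6) and BOA (0.45) rose in ACD+ shoots but did not pass in ACD- shoots (0.51, 0.17 and 0.09). ELF4 (0.7 and 0.72) and FKF1 (0.04 and -0.02) passed with neither. None passed in roots.

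The median change of the photosynthesis probes in treated roots was -0.045 with ACD+ and -0.048 with ACD- bacteria. Dye effects of the ACD+ and ACD- shoots correlated over probes at r = 0.601, and their SD was 0.267 in shoots and 0.0844 in roots.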
